A study of Homo sapiens with 36 samples.

How the data were processed

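Total RNA was measured from PC3M cells, a metastatic derivative of the PC3 human prostate adenocarcinoma line, on human whole-genome expression arrays. Cells were deprived of serum for 16 h and were then left untreated or given 1 of 3 ligands of the MET receptor for 8, 16 or 32 h. The ligands were human hepatocyte growth factor (hHGF) at 1 nM, mouse HGF (mHGF) at 1 nM and NK2, a short natural form of HGF, at 30 nM. Each of the 12 groups held 3 arrays from biological triplicates, 36 arrays in all. Per the labels, the authors processed the arrays with Partek and RMA, and no versions or settings were given. The deposited values are in log2 units, and their range, from 1.52 to 15.2, was checked against that unit. Array medians lay between 5.32 and 5.45.

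The 54675 probe sets comprised 62 controls, 41091 with 1 gene symbol, 1801 with several and 11721 with none. Probe sets with 1 symbol were kept, and each of the 19775 genes was represented by the probe set with the highest mean over all arrays. For 10523 genes there was a choice between probe sets, and 9252 genes had 1. Of the symbols, those of 41037 probe sets were found in a table of current human gene names. No filter on expression was applied. Probe sets without a symbol or with several were left out because they could not be assigned to 1 gene.

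Group means were fitted to all 36 arrays at once with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variances (24 residual and 5.88 prior degrees of freedom). There were 25 contrasts. They set each ligand against the untreated cells of the same time, and averaged over the 3 times. They also set the ligands against each other, the effect of each ligand at 32 h against its effect at 8 h, and untreated cells at 32 h against 8 h. Tests were two-sided and p values were adjusted by Benjamini-Hochberg within each contrast. A gene was called at an adjusted p under 0.05. Changes are log2 differences with the standard error (SE) of the fit, and intervals are 95% intervals. The fit estimates a single spread per gene over all 36 arrays. A gene therefore has the same SE in every comparison of 3 arrays with 3, however much those arrays vary. An SE given with n = 3 is this value and not that of the 3 arrays alone. Residual SDs of the arrays ranged from 0.106 to 0.318. Precision is limited by the number of arrays and by this assumption of equal spread. Replicate numbers were not used as blocks, because the labels tie no number to a shared day.

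The following choices were made before the data were examined. In a contrast at 1 time, the named genes were the 5 most increased and the 5 most decreased called genes whose 3 arrays in 1 group all lay on the same side of the 3 arrays of the other. Unchanged genes meet that condition by chance in 10% of cases for a group of 3 against 3. In averaged contrasts and contrasts between times, the 5 called genes with the largest change in each direction were eligible. Within a list of genes, up to 4 called members with the largest change were eligible. The genes eligible whatever their values included MET, HGF, DUSP6, SPRY2, SPRY4, EGR1, FOSL1, PHLDA1, PLAU, PLAUR, MMP1, CDH1, VIM, CCND1, MYC, CXCL8, EREG, CDKN1A and MKI67.

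The 26 gene lists were also fixed beforehand and held 581 entries, of which 538 were measured. They covered MET receptor and ligand processing, ERK feedback and immediate early genes, the EGFR family, invasion proteases, integrins and laminins, epithelial junctions, mesenchymal genes, actin and SRF-YAP targets, TGF-beta and BMP targets, and angiogenic and guidance genes. Others held chemokines and NF-kB targets, interferon-stimulated genes, G1/S genes, G2/M genes, ribosome biogenesis and MYC targets, p53 targets, FOXO targets, ATF4 and unfolded protein response genes, heat shock genes and hypoxia genes. The last held cholesterol synthesis genes, fatty acid synthesis genes, prostate luminal genes, and markers of endothelial cells, fibroblasts and leukocytes. Each list was tested with camera of limma, which asks whether its members ranked apart from the other genes, at a preset correlation between genes of 0.01 and again with a correlation estimated per list. Adjustment was over 234 tests of ligands against untreated cells and over 234 tests between ligands. The self-contained test fry was run beside it.

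Alternatives were the replicate number as a block, a fit of the compared groups alone, the mean of all probe sets of a gene, genes above the median expression, cyclic loess scaling, array weights and leaving out each array in turn. Data handling used the data.table package, version 1.17.8, and plots used matplotlib 3.10.9 in Python 3.11.15.

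The procedure was tested on simulated data. Of added log2 changes of 0.5, 1 and 2, the fit recovered 34.3%, 98.5% and 100%, and 3.73% of its calls were false. In 20 simulations without any effect, at most 1 gene was called in a contrast.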

Results

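The data cover 36 arrays from PC3M prostate adenocarcinoma cells in 12 groups of 3 biological replicates. HGF binds the receptor tyrosine kinase MET and drives scattering, growth and invasion of epithelial cells, and NK2 is a natural variant that binds the same receptor with a part of these activities. The labels give the purpose as the expression program of HGF in invasion and state that the doses were chosen for equal receptor occupancy. In each of the contrasts 19775 genes were tested, and the median standard error of a change between groups of 3 was 0.142. The correlation between arrays was 0.983 to 0.998 within groups and 0.964 to 0.997 between groups. The array of hHGF at 32 h, replicate 3, had a GAPDH signal 0.97 higher at the 3' than at the 5' end of the transcript, against -0.08 to 0.12 on the other arrays.

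**Figure D1:**
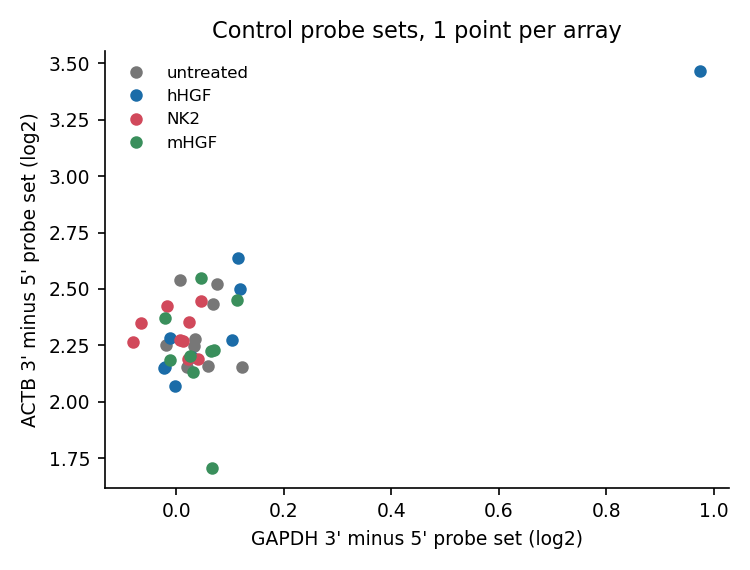
Signal at the 3' minus the 5' end (log2) of the ACTB (vertical axis) and GAPDH (horizontal axis) control probe sets, 1 point per array, coloured by treatment. The array of hHGF at 32 h, replicate 3, lies at 0.97 for GAPDH and 3.47 for ACTB, apart from the others.

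The first question was what human HGF changed within 8 h. MMP1, the interstitial collagenase, rose with hHGF by 1.20 ± 0.17 (SE, n = 3 arrays per group, adjusted p = 0.000158). TNFAIP6, a secreted hyaluronan-binding protein, rose by 1.18 ± 0.16 (adjusted p = 0.000158). The pro-apoptotic BCL2 family member BMF changed by -1.31 ± 0.16 (adjusted p = 2.65e-05) and the growth factor gene BMP3 by -1.16 ± 0.17 (adjusted p = 0.000294). The amino acid and endoplasmic reticulum stress genes driven by ATF4 rose as a list, with 9 of 25 members higher and 0 lower, and 13 and 0 adjusted over the list alone (adjusted p = 3.16e-11; adjusted p = 0.00164 with an estimated correlation). Among them were CHAC1 at 1.07 ± 0.22, which degrades glutathione, and the transcription factor ATF3 at 0.96 ± 0.18. Ribosome biogenesis genes, which include the rRNA-processing factors RRP9 at 0.70 ± 0.17 and NOP2 at 0.68 ± 0.15, also ranked higher, with 5 of 23 members higher and 0 lower, and 10 and 0 adjusted over the list alone (adjusted p = 1e-07; adjusted p = 0.0264 with an estimated correlation). FOXO targets ranked lower (adjusted p = 2.57e-05; adjusted p = 0.139 with an estimated correlation), among them the cyclin gene CCNG2 at -1.09 ± 0.14. In all, limma called 717 genes, 356 higher and 361 lower, of which 21 changed more than 2-fold. The count was 313, 387 and 377 without untreated replicates 1, 2 and 3, and 312, 274 and 260 without hHGF replicates 1, 2 and 3, and it was 279 in a fit of these 6 arrays alone and 1636 with array weights. CXCL8, PLAUR, CCND1 and CDKN1A were called at 0.81, 0.61, 0.39 and 0.46, and each lost its call without any 1 of at least 5 of the 6 arrays, with adjusted p values up to 0.0865, 0.0985, 0.108 and 0.102.

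Mouse HGF was tested at the same time to see how far it acted on human cells. TNFAIP6 rose by 1.06 ± 0.16 (adjusted p = 0.000504), the stromelysin gene MMP3 by 1.03 ± 0.19 (adjusted p = 0.0021) and MMP1 by 0.92 ± 0.17 (adjusted p = 0.00199). PDK4, a kinase that restrains pyruvate oxidation, changed by -1.48 ± 0.25 (adjusted p = 0.000962) and the transcription factor TFEC by -1.35 ± 0.18 (adjusted p = 0.000155). ATF4 targets ranked higher, with 3 of 25 members higher and 0 lower, and 8 and 0 adjusted over the list alone (adjusted p = 3.33e-07; adjusted p = 0.0113 with an estimated correlation), among them the amino acid transporter SLC7A5 at 0.77 ± 0.12. Hypoxia and glycolysis genes ranked lower (adjusted p = 8.33e-05; adjusted p = 0.176 with an estimated correlation), among them the crosslinking enzyme LOX at -0.71 ± 0.15. The 695 called genes were 178 higher and 517 lower. No gene passed when limma was fitted to these 6 arrays alone, so the calls named here rest on the spread estimated over all groups, where 3794 genes had an unadjusted p under 0.05. Array weights gave 429. Single arrays moved the count to 306, 397 and 417 without untreated replicates 1, 2 and 3, and 178 without mHGF replicate 1. That mHGF array stood apart from its group, with a residual SD of 0.225 against 0.183 and 0.170, an ACTB difference of 1.71 against 2.23 and 2.20, and a weight of 0.213.

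NK2 at 8 h was set against untreated cells to see which part of the response it shared. TGFBI, a matrix protein induced by TGF-beta, rose by 2.40 ± 0.22 (SE, n = 3, adjusted p = 7.29e-09) and the protease inhibitor SERPINB7 by 2.17 ± 0.20 (adjusted p = 1.16e-08). The immediate early transcription factor EGR1 rose by 2.12 ± 0.21 (adjusted p = 2.76e-08), a direction seen in 2 of its 3 probe sets. The metal-binding protein gene MT1F rose by 2.01 ± 0.17 (adjusted p = 1.67e-09). HMGCS1, an enzyme at the start of the mevalonate pathway, changed by -2.15 ± 0.11 (adjusted p = 1.07e-14), the stress cytokine GDF15 by -1.91 ± 0.14 (adjusted p = 1.09e-10) and the keratin KRT20 by -2.10 ± 0.24 (adjusted p = 8.5e-07). Limma called 1502 genes, 675 higher and 827 lower, with 108 changed more than 2-fold. Leaving out 1 array gave 1001 without untreated replicate 1, and 887, 931 and 992 without NK2 replicates 1, 2 and 3, and array weights gave 2635.

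Cholesterol synthesis genes ranked lower with NK2 at 8 h, with 0 of 18 members higher and 15 lower, and 0 and 16 adjusted over the list alone, at a median of -0.81 (adjusted p = 8.25e-34; adjusted p = 3.01e-07 with an estimated correlation). MSMO1, ACAT2 and SQLE of that pathway changed by -1.53 ± 0.10, -1.47 ± 0.13 and -1.41 ± 0.11. Fatty acid synthesis genes ranked lower as well, with 0 of 13 members higher and 9 lower, and 0 and 9 adjusted over the list alone (adjusted p = 1.74e-11; adjusted p = 8.86e-06 with an estimated correlation), among them the acetyl-CoA synthetase gene ACSS2 at -0.95 ± 0.12. TGF-beta and BMP targets ranked higher, with 7 of 21 members higher and 1 lower, and 10 and 1 adjusted over the list alone (adjusted p = 1.07e-05; adjusted p = 0.00772 with an estimated correlation), led by PMEPA1, a feedback inhibitor of SMAD signalling, at 1.39 ± 0.14 and the activin subunit gene INHBA at 0.88 ± 0.20. Mitotic genes ranked higher, with 18 of 32 members higher and 0 lower, and 26 and 0 adjusted over the list alone (adjusted p = 3.16e-17; adjusted p = 0.00753 with an estimated correlation), and the mitotic kinesins KIF20A and KIF23 stood at 0.63 ± 0.10 and 0.63 ± 0.11. Mesenchymal genes were called at the preset correlation only (adjusted p = 0.00353; adjusted p = 0.129 with an estimated correlation), with fibronectin, FN1, at 1.11 ± 0.20.

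**Figure D2:**
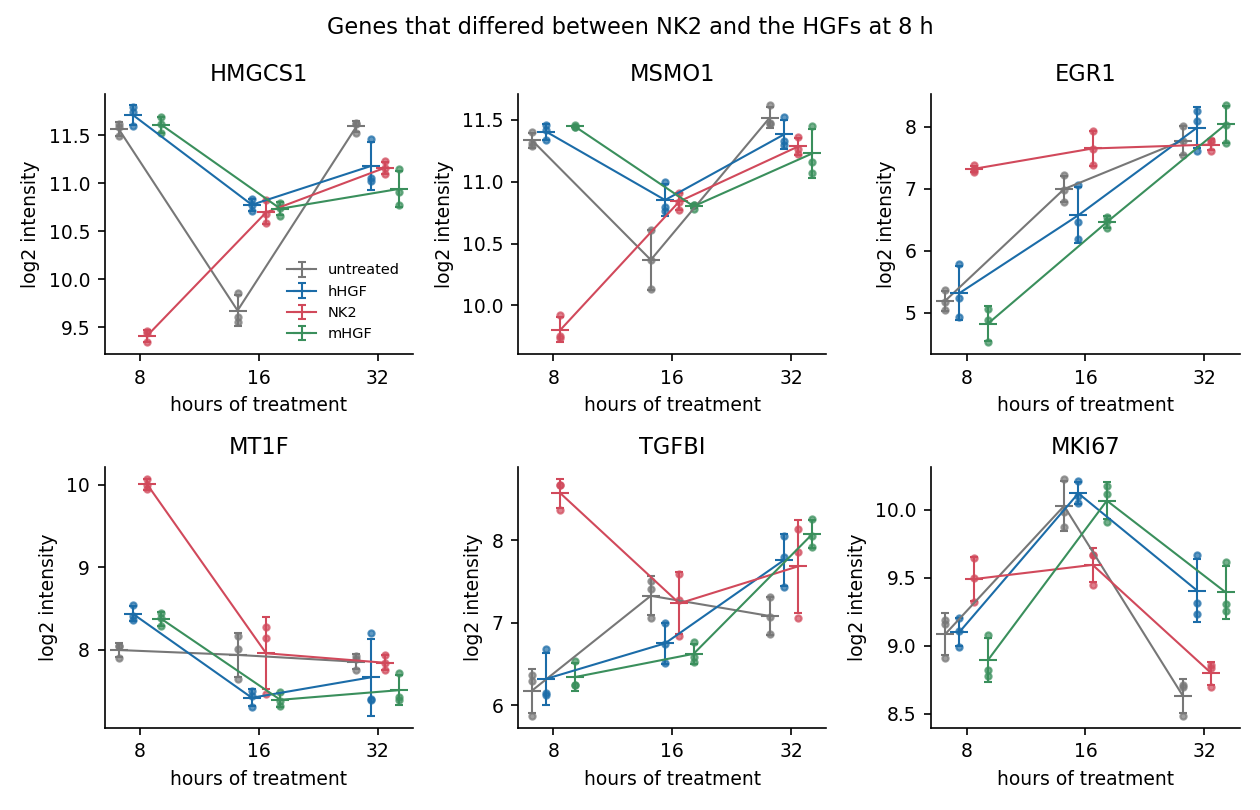
Log2 intensity (vertical axis) of 6 genes at 8, 16 and 32 h of treatment (horizontal axis, evenly spaced) by treatment; points are arrays and bars the mean ± SD, n = 3 arrays per group. At 8 h HMGCS1 with NK2 lies 2.30 below hHGF, and MT1F, EGR1 and TGFBI lie above both HGFs.

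At 16 h the comparison with untreated cells gave the most calls with each ligand. Limma called 3890 genes with hHGF, 2031 higher and 1859 lower. With NK2 it called 3075, of which 1663 were higher and 1412 lower, and with mHGF 3675, of which 1855 were higher and 1820 lower. LXN, an inhibitor of carboxypeptidases, changed by -2.82 ± 0.23, -3.17 ± 0.23 and -3.30 ± 0.23 with hHGF, NK2 and mHGF (adjusted p = 1.58e-09 with hHGF), and the Ras-related gene RASD1 by -2.77 ± 0.30, -3.13 ± 0.30 and -3.11 ± 0.30. The glutamate transporter SLC1A3 rose by 1.90 ± 0.15 with NK2 (adjusted p = 1.59e-09) and 2.07 ± 0.15 with mHGF, the latter in 1 of its 2 probe sets. IFIT1, an interferon-induced gene, rose by 2.00 ± 0.19 with hHGF (adjusted p = 1.61e-08), and LUZP2 and RFX6 rose with hHGF by 2.42 ± 0.26 and 2.30 ± 0.25. MMP1 was lower in all 3 comparisons, at -1.35 ± 0.17, -1.86 ± 0.17 and -1.69 ± 0.17, and so was the chemokine gene CXCL8, at -1.24 ± 0.20, -1.28 ± 0.20 and -1.79 ± 0.20. The epithelial cadherin CDH1 changed by -0.82 ± 0.15, -0.67 ± 0.15 and -0.92 ± 0.15, and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by -1.01 ± 0.12 with hHGF and -1.02 ± 0.12 with mHGF.

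The untreated 16 h arrays stood apart from the untreated arrays of the other times, with 4455 genes called between them and the untreated 8 h and 32 h groups. Against the mean of these other untreated groups, a comparison chosen after that was seen, the calls at 16 h were 4178 for hHGF, 925 for NK2 and 2458 for mHGF. Genes called in both comparisons with the same direction numbered 1457, 257 and 946, and 224, 107 and 141 were called with opposite directions. LXN, MMP1 and CXCL8 then stood at 0.65, 0.72 and 0.97 with hHGF, and the calls of RASD1 were lost. CDH1 kept its calls against this control, at -0.82, -0.67 and -0.92, and SPRY4 did with hHGF and mHGF. SLC1A3, IFIT1, LUZP2 and RFX6 were called at smaller changes, with SLC1A3 at 0.62 with NK2 and 0.79 with mHGF, and IFIT1, LUZP2 and RFX6 at 0.76, 1.32 and 1.34 with hHGF. Without untreated replicate 2 the counts fell to 2309, 1852 and 2350, and with array weights they were 6333, 5989 and 6827.

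**Figure D3:**
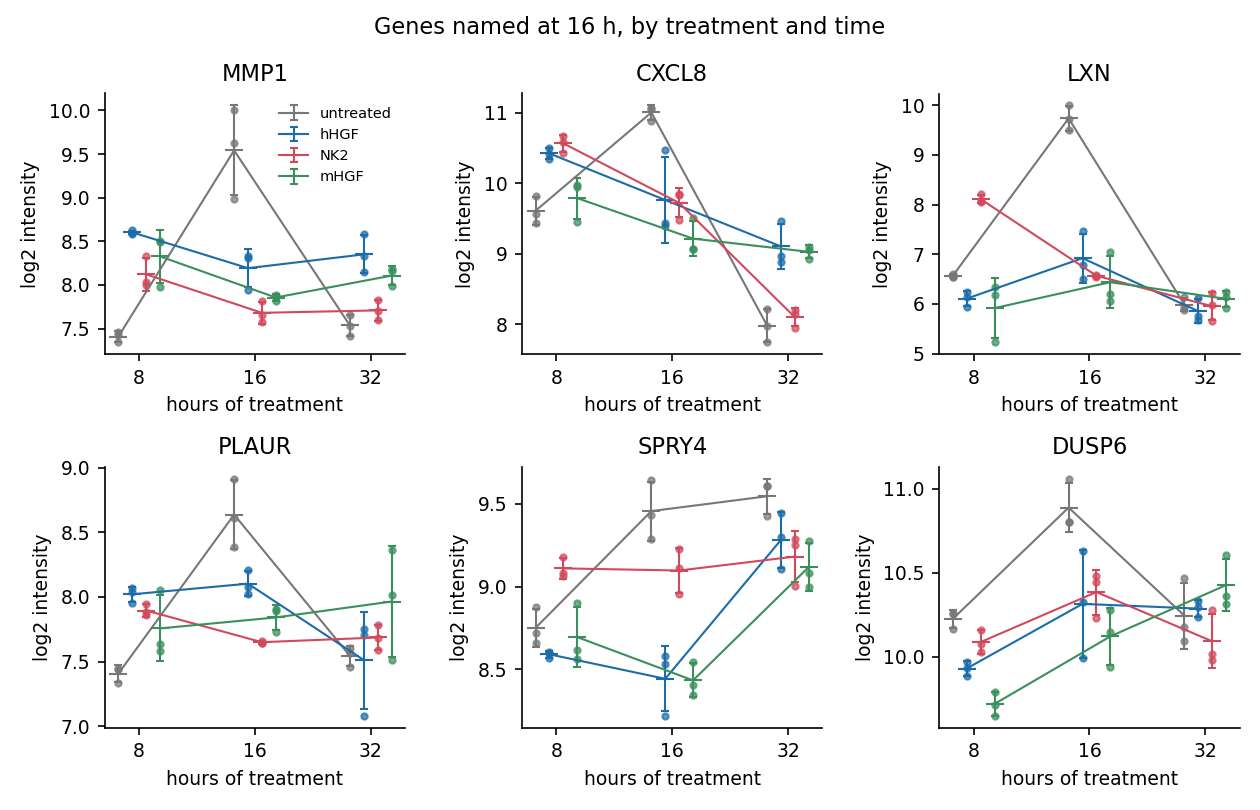
Log2 intensity (vertical axis) of 6 genes at 8, 16 and 32 h of treatment (horizontal axis, evenly spaced) by treatment; points are arrays and bars the mean ± SD, n = 3 arrays per group. At 16 h LXN with hHGF changed by -2.82 and MMP1 by -1.35 against untreated cells.

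Among the gene lists at 16 h, heat shock genes, which encode chaperones, ranked higher with all 3 ligands. With hHGF this covered 8 of 10 members higher and 0 lower, and 9 and 0 adjusted over the list alone (adjusted p = 4.09e-10; adjusted p = 0.00225 with an estimated correlation), and the list kept its call against the other untreated groups (adjusted p = 1.02e-05). HSPH1 and CHORDC1 of that list changed by 1.01 ± 0.13 and 1.04 ± 0.12 with hHGF, and by 1.01 ± 0.13 and 0.96 ± 0.12 with NK2. Ribosome biogenesis genes ranked higher with hHGF, with 12 of 23 members higher and 0 lower, and 17 and 0 adjusted over the list alone (adjusted p = 9.74e-10; adjusted p = 0.0113 with an estimated correlation), among them UTP20 at 1.06 ± 0.10, and they kept the call against the other control with hHGF (adjusted p = 0.0187) and mHGF (0.0109) but not with NK2 (0.148). Genes of G1/S and DNA replication ranked higher with hHGF, with 26 of 33 members higher and 0 lower, and 31 and 0 adjusted over the list alone; this call was made at the preset correlation only (adjusted p = 3.91e-18; adjusted p = 0.111 with an estimated correlation). Called higher with NK2 and mHGF as well, the list kept these calls against the other control (adjusted p = 0.00162 and 2.71e-14). Untreated 16 h arrays differed among themselves in the mean of this list, with an SD of 0.405 against 0.0825 with hHGF. Against the other control the list kept its call with hHGF too (adjusted p = 7.64e-12). Its members included the replication clamp PCNA at 1.05 ± 0.18 and E2F2 at 1.15 ± 0.25.

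Some other lists at 16 h depended on the choice of control. Mitotic genes ranked higher with hHGF and mHGF against both controls, with adjusted p = 5.06e-06 and 0.0276 against untreated 16 h cells at the preset correlation only, and 1.34e-45 and 2.8e-50 against the other control. With NK2 they were called against the other control alone, as higher (9.36e-47 against 0.135). In untreated cells the mean of this list was 9.484, 9.964 and 9.221 at 8, 16 and 32 h, against 9.894 with NK2 at 16 h. The values against the other control therefore include a difference of time and do not stand for ligand action alone. ATF4 targets ranked lower with hHGF, with 0 of 25 members higher and 14 lower, and 0 and 16 adjusted over the list alone (adjusted p = 8.55e-07; adjusted p = 0.0139 with an estimated correlation), and asparagine synthetase, ASNS, stood at -1.20 ± 0.18. Against the other untreated groups the adjusted p values of that list were 0.161, 0.431 and 0.784 with hHGF, NK2 and mHGF. Invasion proteases and their inhibitors ranked lower with hHGF, with 0 of 25 members higher and 11 lower, and 0 and 15 adjusted over the list alone (adjusted p = 6.92e-06; adjusted p = 0.0276 with an estimated correlation), among them the collagenase MMP13 at -1.77 ± 0.26, and against the other control the values were 0.971, 0.985 and 0.851. Cholesterol synthesis genes ranked higher with hHGF, with 14 of 18 members higher and 1 lower, and 14 and 1 adjusted over the list alone (adjusted p = 6.17e-13; adjusted p = 0.000424 with an estimated correlation), and DHCR7 stood at 1.15 ± 0.12. Against the other control they ranked lower with each ligand (adjusted p = 0.000609, 6.44e-15 and 7.54e-08). Fatty acid synthesis genes ranked higher with hHGF (adjusted p = 2.39e-06; adjusted p = 0.000693 with an estimated correlation), with fatty acid synthase, FASN, at 1.00 ± 0.12, and lost the call against the other control (0.865). TGF-beta targets, with INHBA at -1.80 ± 0.20, ranked lower (adjusted p = 0.00117; adjusted p = 0.0431 with an estimated correlation) and lost the call (0.669), and with NK2 they ranked higher against the other control (0.000601).

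ERK feedback genes, which include the phosphatase gene DUSP5 at -1.64 ± 0.18, ranked lower with mHGF, with 0 of 27 members higher and 13 lower, and 0 and 17 adjusted over the list alone (adjusted p = 4.42e-10; adjusted p = 0.00416 with an estimated correlation), and kept the call against the other untreated groups (adjusted p = 0.000919). With hHGF the ERK list was called against untreated 16 h cells (adjusted p = 1e-07; adjusted p = 0.0113 with an estimated correlation) and not against the others (0.137), and the same held with NK2 at the preset correlation only (adjusted p = 7.29e-05; 0.799 against the others). Integrins and laminins ranked lower with hHGF, with 1 of 21 members higher and 13 lower, and 1 and 15 adjusted over the list alone (adjusted p = 7.3e-06; adjusted p = 0.0431 with an estimated correlation) and 0.0166 against the others, while with NK2 their call (adjusted p = 0.00797) was lost (0.683), and ITGB4, an epithelial laminin receptor, stood at -1.35 ± 0.14. Actin and SRF-YAP targets, with CCN2 at -0.83 ± 0.12, ranked lower with NK2 at the preset correlation only (adjusted p = 0.0178, and 0.125 with an estimated correlation). This was not particular to NK2, since the list was also called lower with hHGF and mHGF. Its mean was 8.797 in untreated 16 h cells and 8.587, 8.621 and 8.597 with hHGF, NK2 and mHGF. Against the others the call was kept with NK2 (adjusted p = 0.0292) and lost with hHGF and mHGF (0.0695 and 0.0519).

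At 32 h, hHGF was compared with untreated cells for its late effects. The neuropeptide precursor gene NTS rose by 2.04 ± 0.20 (SE, n = 3, adjusted p = 9.35e-08) and the chemokine gene CXCL1 by 1.69 ± 0.16 (adjusted p = 7.45e-08). HSD17B2, which inactivates sex steroids, changed by -1.49 ± 0.10 (adjusted p = 9.7e-11) and the phospholipid flippase ATP8A2 by -1.61 ± 0.21 (adjusted p = 2.04e-05). MMP1 and CXCL8 rose by 0.81 ± 0.17 and 1.12 ± 0.20, the proliferation marker MKI67 rose by 0.77 ± 0.12 in 3 of its 4 probe sets, and the cyclin gene CCND1 changed by -0.59 ± 0.10. Mitotic genes ranked higher, with 18 of 32 members higher and 0 lower, and 21 and 0 adjusted over the list alone (adjusted p = 3.22e-11; adjusted p = 0.0315 with an estimated correlation), led by HMMR at 0.84 ± 0.13. Chemokines and NF-kB targets ranked higher at the preset correlation (adjusted p = 0.0199; adjusted p = 0.163 with an estimated correlation). Of the 2559 called genes 1260 were higher and 1299 lower, 49.2% higher, and cyclic loess scaling gave 2627 with 59.9% higher. In a fit of these 6 arrays alone 22 genes passed, and NTS, CXCL1, HSD17B2 and ATP8A2 kept their calls while those of MMP1, CXCL8, MKI67 and CCND1 were lost. With the mean of all probe sets MKI67 lost its call too, at 0.30. The count was 1514, 1516 and 1606 without untreated replicates 1, 2 and 3, and 3875 and 1112 without hHGF replicates 1 and 3; replicate 3 of hHGF is the array with the GAPDH difference of 0.97, and its ACTB difference was 3.47 against 1.71 to 2.64 on the others.

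With mHGF at 32 h, SERPINB7 rose by 1.85 ± 0.20 (adjusted p = 9.38e-07), CXCL1 by 1.62 ± 0.16 (adjusted p = 1.34e-07) and the tissue plasminogen activator gene PLAT by 1.49 ± 0.23 (adjusted p = 0.000111). TCN1, which encodes a cobalamin carrier, changed by -1.93 ± 0.17 (adjusted p = 1.72e-08), and KRT20 by -1.58 ± 0.24 (adjusted p = 9.92e-05). MKI67 and CXCL8 rose by 0.76 ± 0.12 and 1.05 ± 0.20, and SPRY2 and MYC changed by -0.58 ± 0.12 and -0.43 ± 0.09. Mitotic genes ranked higher, with 20 of 32 members higher and 0 lower, and 24 and 0 adjusted over the list alone (adjusted p = 1.41e-17; adjusted p = 0.00718 with an estimated correlation), among them the checkpoint kinase BUB1 at 0.55 ± 0.10. Hypoxia genes ranked higher, with 10 of 29 members higher and 0 lower, and 13 and 0 adjusted over the list alone (adjusted p = 2.9e-09; adjusted p = 0.0431 with an estimated correlation), led by the collagen-modifying enzyme PLOD2 at 1.23 ± 0.14. Cholesterol synthesis genes ranked lower, with 0 of 18 members higher and 5 lower, and 0 and 9 adjusted over the list alone (adjusted p = 3.54e-06; adjusted p = 0.0103 with an estimated correlation), and LSS stood at -0.78 ± 0.12. Limma called 1676 genes, 538 higher and 1138 lower, 32.1% higher, and cyclic loess gave 1423 with 47.9% higher. The count was 775 without untreated replicate 1, and 778 without mHGF replicate 2, and 3652 with array weights.

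NK2 at 32 h gave 11 called genes, 9 higher and 2 lower, from 1144 with an unadjusted p under 0.05. PI3, an inhibitor of elastase, rose by 0.76 ± 0.12 (SE, n = 3, adjusted p = 0.00627) and S100A10, a partner of annexin, by 0.74 ± 0.12 (adjusted p = 0.00847). The growth factor gene TGFB2 changed by -0.77 ± 0.15 (adjusted p = 0.0369). Fitted to the 6 arrays alone limma called 0 genes, with array weights 382 and with the mean of all probe sets 7. Single arrays moved the count to 1, 2 and 0 without untreated replicates 1, 2 and 3, and 0, 0 and 38 without NK2 replicates 1, 2 and 3. PI3, S100A10 and TGFB2 each lost the call without any 1 of at least 3 of the arrays, with adjusted p values up to 0.177, 0.242 and 0.556. Prostate luminal genes ranked lower, with 0 of 13 members higher and 0 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.000722; adjusted p = 0.00753 with an estimated correlation), a call lost among genes above the median expression (adjusted p = 0.176). Cholesterol synthesis genes ranked lower, with 0 of 18 members higher and 0 lower, and 0 and 1 adjusted over the list alone (adjusted p = 0.000382; adjusted p = 0.0431 with an estimated correlation).

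**Figure D4:**
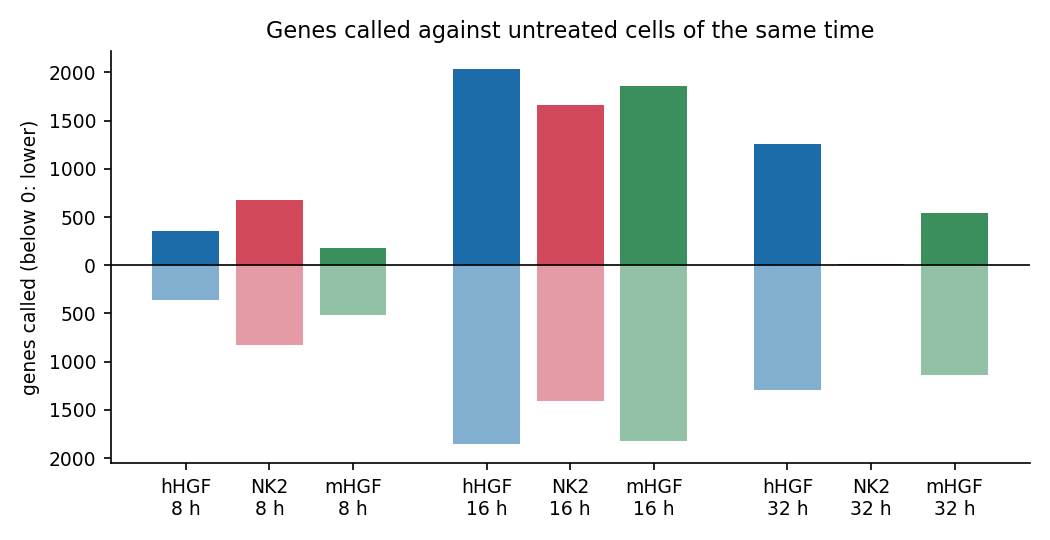
Number of genes called higher (upward) and lower (downward) against untreated cells of the same time, by ligand and time, with 3 arrays per group. NK2 has 3075 calls at 16 h and 11 at 32 h.

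**Figure D5:**
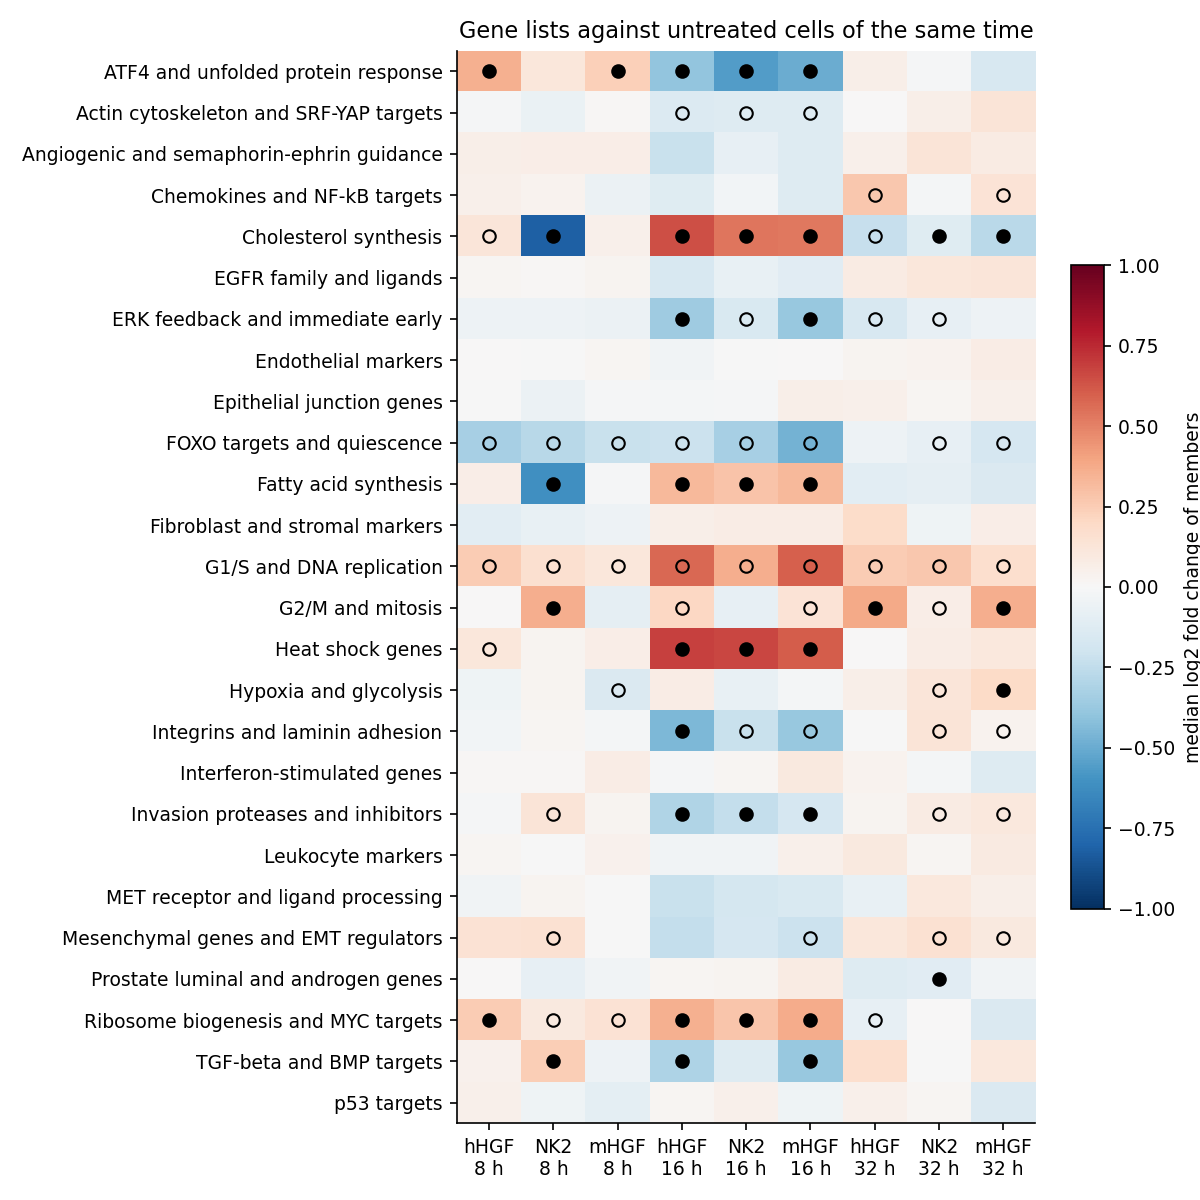
Gene lists (vertical axis) by ligand and time, with colour for the median log2 change of the members; filled dots mark lists called with an estimated correlation too and open dots lists called at 0.01 alone. Cholesterol synthesis is at -0.81 with NK2 at 8 h.

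Averaged over the 3 times, the contrasts tested the mean change, which a change at 1 time can also give. NTS rose by 1.41 ± 0.11 with hHGF (adjusted p = 8.13e-10) and 1.03 ± 0.11 with mHGF (adjusted p = 2.54e-07), and HSD17B2 changed by -1.07 ± 0.06 with hHGF (adjusted p = 2.76e-13). BMF and the kinase gene JAK3 changed by -1.09 ± 0.09 and -1.01 ± 0.14 with hHGF, and JAK3 by -1.09 ± 0.14 with mHGF. With NK2, REG4, a secreted lectin, rose by 1.03 ± 0.10 (adjusted p = 5.03e-08), TGFBI by 0.97 ± 0.13 and EGR1 by 0.90 ± 0.12, and the transcription factor CREB5 changed by -0.82 ± 0.08 (adjusted p = 5.19e-08). The change of EGR1 was 2.12, 0.65 and -0.06 at 8, 16 and 32 h, so its mean does not stand for a change at every time. Limma called 4072 genes for hHGF, 2148 for NK2 and 3249 for mHGF. With 8 h and 32 h only, an alternative chosen after the data were seen, the counts were 2169, 811 and 1885. The count for NK2 was 3397 in a fit of the compared groups alone, and with array weights those for NK2 and mHGF were 4631 and 4928. With hHGF, 39 genes were called higher and 41 lower at all 3 times, with mHGF 4 and 45, and with NK2 limma called 0 at all 3 times, where 11 were called at 32 h alone.

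The effect at 32 h was also tested against that at 8 h. With hHGF the zinc importer SLC39A10 differed by 1.78 ± 0.28 (adjusted p = 0.000602), NTS by 1.72 ± 0.28 (adjusted p = 0.000744) and ATF5, a stress-response transcription factor, by -1.50 ± 0.19 (adjusted p = 7.31e-05). With NK2 the growth factor carrier FGFBP1 differed by 1.81 ± 0.14 (adjusted p = 4.09e-09), GDF15 by 1.92 ± 0.20 (adjusted p = 8.01e-07), MT1F by -2.02 ± 0.24 (adjusted p = 4.31e-06) and TGFB2 by -1.99 ± 0.21 (adjusted p = 8.37e-07). With mHGF, SLC39A10 differed by 1.61 ± 0.28 (adjusted p = 0.00154), ATF3 by -1.45 ± 0.26 (adjusted p = 0.00205) and MKI67 by 0.95 ± 0.18 (adjusted p = 0.00286). CCND1 differed by -0.98 ± 0.15 with hHGF. Limma called 811, 272 and 600 genes for hHGF, NK2 and mHGF. The counts were 63, 587 and 160 in a fit of the compared groups alone, and with array weights 1302, 1054 and 1082. For hHGF 44.1% were higher, and with cyclic loess 64.0% of 833. Replicate 3 of hHGF at 32 h, included here, is the array with the GAPDH difference of 0.97. Single arrays moved the count for hHGF to 438 and 520 without untreated 8 h replicates 1 and 3, 413, 450 and 444 without untreated 32 h replicates 1, 2 and 3, 418, 512 and 443 without hHGF 8 h replicates 1, 2 and 3, and 2141, 1498 and 472 without hHGF 32 h replicates 1, 2 and 3. For NK2 it was 174 and 161 without untreated 32 h replicates 1 and 2, 163 and 161 without NK2 8 h replicates 1 and 2, and 171 and 172 without NK2 32 h replicates 1 and 2, and for mHGF 357 and 346 without untreated 8 h replicates 2 and 3, 247 and 338 without untreated 32 h replicates 1 and 2, 231 and 974 without mHGF 8 h replicates 1 and 2, and 332 and 384 without mHGF 32 h replicates 2 and 3.

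Human HGF was then set directly against NK2 to find where the full ligand and its variant differed. At 8 h HMGCS1 was 2.30 ± 0.11 higher with hHGF (SE, n = 3, adjusted p = 1.7e-15), the lipase gene LIPG 2.25 ± 0.14 (adjusted p = 1.24e-12) and FGFBP1 1.89 ± 0.10 (adjusted p = 6.68e-14). TGFBI differed by -2.25 ± 0.22 (adjusted p = 2.41e-08), EGR1 by -2.00 ± 0.21 (adjusted p = 7.32e-08) and MT1F by -1.57 ± 0.17 (adjusted p = 1.97e-07). Cholesterol synthesis genes ranked higher with hHGF, with 17 of 18 members higher and 0 lower, and 17 and 0 adjusted over the list alone (adjusted p = 2.53e-45; adjusted p = 1.74e-08 with an estimated correlation), and so did fatty acid synthesis genes, with 9 of 13 members higher and 0 lower, and 10 and 0 adjusted over the list alone (adjusted p = 8.67e-16; adjusted p = 4.46e-07 with an estimated correlation). Mitotic genes ranked lower with hHGF than with NK2, with 0 of 32 members higher and 16 lower, and 0 and 23 adjusted over the list alone (adjusted p = 6.08e-18; adjusted p = 0.0134 with an estimated correlation), and KIF20A differed by -0.69 ± 0.10. Limma called 1172 genes, 665 higher and 507 lower, and array weights gave 2490. Without single arrays the count was 725, 723 and 779 without hHGF replicates 1, 2 and 3, and 680 and 673 without NK2 replicates 1 and 2.

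At 16 h the same contrast called 263 genes, 121 higher and 142 lower. NTS was 1.39 ± 0.20 higher with hHGF (SE, n = 3, adjusted p = 0.00018), and HSD17B2 differed by -1.22 ± 0.10 (adjusted p = 8.02e-09). SPRY4 and EGR1 differed by -0.65 ± 0.12 and -1.08 ± 0.21, and both lost the call in a fit of these 6 arrays alone. EGR1 also lost it without hHGF replicate 3 (adjusted p = 0.0612) or NK2 replicate 1 (0.0548). Both follow ERK activity, which was not measured, and other such genes were mixed. Against untreated 16 h cells, with hHGF and NK2, SPRY2 stood at -0.41 and -0.13 and PHLDA1 at -0.56 and -0.42. DUSP6 stood at -0.57 and -0.50, and FOSL1 at -0.77 and -0.94. Mitotic genes ranked higher with hHGF, with 7 of 32 members higher and 0 lower, and 22 and 0 adjusted over the list alone (adjusted p = 6.45e-23; adjusted p = 0.00375 with an estimated correlation), and the kinesin CENPE differed by 0.63 ± 0.14. The count was 92 in the fit of 6 arrays, 433 among genes above the median expression and 1040 with array weights. Single arrays moved it to 125, 134 and 114 without hHGF replicates 1, 2 and 3, and 94, 78 and 79 without NK2 replicates 1, 2 and 3.

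At 32 h the contrast of hHGF with NK2 called 1974 genes, 827 higher and 1147 lower. NTS was 1.58 ± 0.20 higher with hHGF (SE, n = 3, adjusted p = 1.71e-05), the interferon-induced genes IFI44 and DDX60 were 1.69 ± 0.19 and 1.44 ± 0.20 higher, and ATP8A2 differed by -1.34 ± 0.21 (adjusted p = 0.000297). MKI67 was 0.61 ± 0.12 higher, in 1 of its 4 probe sets. Mitotic genes ranked higher at the preset correlation only (adjusted p = 2.25e-08; adjusted p = 0.165 with an estimated correlation). Only NTS passed in a fit of these 6 arrays alone, a count of 1, and IFI44, DDX60, ATP8A2 and MKI67 lost their calls, MKI67 also with the mean of all probe sets. Cyclic loess gave 2026 genes with 59.7% higher against 41.9%. The count was 3682, 2962 and 423 without hHGF replicates 1, 2 and 3, and 905, 823 and 1092 without NK2 replicates 1, 2 and 3. Many of the calls may rest on hHGF replicate 3, the array with the GAPDH difference of 0.97.

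Human and mouse HGF were compared to see whether the ligands of the 2 species differed on human cells. At 16 h limma called 0 genes between them, with 1353 at an unadjusted p under 0.05, a smallest adjusted p of 0.400 and 18 genes with array weights. The 95% intervals of the difference at 16 h were -0.22 to 0.15 for MET, -0.004 to 0.68 for MMP1, -0.06 to 0.45 for the ERK phosphatase DUSP6 and -0.20 to 0.31 for MKI67. At 8 h 351 genes were called, 176 higher and 175 lower, among them the ribosomal RNA precursor RNA45SN5 at -1.03 ± 0.15 (adjusted p = 0.00108) and the mitochondrial gene COX3 at -0.87 ± 0.12 (adjusted p = 0.000197). None passed in a fit of these 6 arrays alone by limma, where the fit of all groups had 3575 at an unadjusted p under 0.05. Cyclic loess gave 165 with 36.4% higher against 50.1%, and genes above the median expression gave 322 with 81.1% higher, so the balance of directions rests on the setting. The count was 130, 45 and 87 without hHGF replicates 1, 2 and 3, and 60 without mHGF replicate 1; that mHGF array stood apart from its group. MMP1 and MET were not called at 8 h, with intervals of -0.06 to 0.62 and -0.21 to 0.16.

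At 32 h limma called 2394 genes between the HGFs of the 2 species, 1551 higher and 843 lower with hHGF. PLAT differed by -1.33 ± 0.23 (SE, n = 3, adjusted p = 0.00085), the growth factor binding protein IGFBP3 by -1.31 ± 0.19 (adjusted p = 0.000242), CALCRL, a peptide hormone receptor, by 1.60 ± 0.28 (adjusted p = 0.000827) and SPRY2 by 0.78 ± 0.12 (adjusted p = 0.000377). CXCL8 and MKI67 were not called, with intervals of -0.33 to 0.48 and -0.24 to 0.27. Integrins and laminins ranked lower with hHGF at the preset correlation only (adjusted p = 0.000101; adjusted p = 0.165 with an estimated correlation). Fitted to these 6 arrays alone limma called 0 genes and with array weights 1317. The calls named here therefore rest on the spread of all groups, with 5269 at an unadjusted p under 0.05. The count was 3623 and 682 without hHGF replicates 1 and 3, and 933 and 1567 without mHGF replicates 2 and 3. Replicate 3 of hHGF is the array with the GAPDH difference of 0.97 and an array weight of 0.091. Many of these calls may rest on that array and not on the species of the ligand.

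Averaged over times, hHGF and NK2 differed in 1417 genes, 739 higher and 678 lower. FGB, a fibrinogen chain, was 1.15 ± 0.10 higher with hHGF (adjusted p = 5.12e-09), and HSD17B2 and REG4 differed by -1.07 ± 0.06 (adjusted p = 2.88e-13) and -1.05 ± 0.10 (adjusted p = 2.33e-08). Between mHGF and NK2, 348 genes were higher and 1161 lower, with FGFBP1 at 0.75 ± 0.06 (adjusted p = 9.79e-10), HMGCS1 at 0.67 ± 0.06 (adjusted p = 2.29e-08) and EGR1 at -1.12 ± 0.12 (adjusted p = 4.94e-07). These 2 means did not hold at 32 h: HMGCS1 stood at 11.61 with mHGF and 9.41 with NK2 at 8 h but at 10.94 and 11.16 at 32 h, and EGR1 at 4.83 and 7.32 at 8 h but at 8.03 and 7.71 at 32 h. For HMGCS1 the arrays already overlapped at 16 h, at 10.662, 10.743 and 10.798 with mHGF and 10.825, 10.675 and 10.589 with NK2. Those of EGR1 at 16 h lay at 6.545, 6.477 and 6.359 with mHGF and 7.934, 7.375 and 7.631 with NK2. Cholesterol synthesis genes ranked higher than with NK2 for hHGF, with 13 of 18 members higher and 0 lower, and 15 and 1 adjusted over the list alone (adjusted p = 2.72e-21; adjusted p = 7.44e-06 with an estimated correlation), and for mHGF, with 9 of 18 members higher and 0 lower, and 11 and 0 adjusted over the list alone (adjusted p = 2.07e-17; adjusted p = 3.21e-05 with an estimated correlation). The difference lay mainly at 8 h and did not hold at 32 h. The mean of the list with hHGF, mHGF and NK2 was 10.01, 9.95 and 8.95 at 8 h. It was 9.67, 9.61 and 9.56 at 16 h, and 9.80, 9.71 and 9.88 at 32 h. Between the HGFs of both species 2473 genes were called, 1702 higher with hHGF, among them IFI44 at 0.78 ± 0.11 in 1 of its 2 probe sets and COX3 at -0.53 ± 0.07 (adjusted p = 2.69e-05). With array weights hHGF and NK2 differed in 2508 genes and mHGF and NK2 in 3609, and a fit of the groups alone gave 746 between the HGFs. Of the calls between mHGF and NK2 23.1% were higher, and 37.7% of 1092 with cyclic loess.

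The responses to the ligands were compared across genes, which are not independent replicates, and shared untreated arrays alone give a correlation. In simulations of unchanged groups the correlation was 0.5 and the covariance 0.0113. At 8 h r was 0.531 between hHGF and mHGF, 0.494 between hHGF and NK2 and 0.438 between NK2 and mHGF, with covariances of 0.0273, 0.0289 and 0.0261. The values of r at 16 h were 0.885, 0.814 and 0.877 and the covariances 0.0978, 0.0848 and 0.0914. At 32 h they were 0.485, 0.350 and 0.419, with covariances of 0.0348, 0.0153 and 0.0165. Of the genes called at 8 h, 46 were higher and 178 lower with both HGFs, where independent calls give 3.2 and 9.4. For hHGF and NK2 the counts were 112 and 143 against 12.2 and 15.1, and 8 genes moved in opposite directions. At 16 h 1512 genes were higher and 1306 lower with both HGFs, against 190.5 and 171.1. In 20 simulations without any effect, at most 1 gene was called in a contrast. They drew independent noise with the same spread on all arrays, so they do not cover unequal arrays or a shift of the untreated group. Part of the excess may come from the shared untreated arrays, since 3 arrays per time do not leave 2 for each ligand. All 3 ligands called 102 genes in the same direction at 8 h, 2029 at 16 h and 7 at 32 h.

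Untreated cells were compared between 32 h and 8 h for changes in culture without ligand. EGR1 rose by 2.58 ± 0.21 (SE, n = 3, adjusted p = 2.29e-09), in 2 of its 3 probe sets. CXCL1 changed by -2.00 ± 0.16 (adjusted p = 2.29e-09), the cytokine gene IL1B by -2.06 ± 0.21 (adjusted p = 2.57e-07), IGFBP3 by -1.78 ± 0.19 (adjusted p = 4.05e-07) and CXCL8 by -1.63 ± 0.20 (adjusted p = 3.25e-06). SPRY4 and MYC rose by 0.80 ± 0.12 and 0.45 ± 0.09. Limma called 2166 genes, 897 higher and 1269 lower, and array weights gave 3826. Among genes above the median expression 1368 were called, 58.8% of them higher against 41.4% in the main fit, and single arrays moved the count to 1384 without untreated 8 h replicate 3, and 1319 and 1135 without untreated 32 h replicates 1 and 2.

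No call against untreated cells was made for 9 lists, and their smallest adjusted p values were these. For the genes of the MET receptor and its ligand processing it was 0.069, for the EGFR family 0.0725, for p53 targets 0.0935, for angiogenic and guidance genes 0.0943 and for epithelial junction genes 0.244. For interferon-stimulated genes it was 0.0522. For the markers of leukocytes, fibroblasts and endothelial cells it was 0.173, 0.176 and 0.393, and none of the 13 measured leukocyte markers was called by limma. MET itself was not called against untreated cells of the same time in the main fit. At 16 h it was called with hHGF among genes above the median expression, with cyclic loess and with array weights (adjusted p = 0.0438, 0.046 and 0.0261), and with mHGF with array weights (0.0356). Averaged over times it was called with hHGF, at -0.16 ± 0.05 (adjusted p = 0.0261), a call lost without any 1 of 5 arrays (adjusted p up to 0.0552), in a fit of the compared groups alone and with 8 h and 32 h only. Against the untreated 8 h and 32 h groups MET was called at 16 h, at -0.33 with hHGF (adjusted p = 0.00269) and -0.30 with mHGF (adjusted p = 0.00987). HGF was called at 16 h with hHGF at 0.54 ± 0.18 and with mHGF at 0.69 ± 0.18; with hHGF it lost the call without any 1 of 5 of the 6 arrays (adjusted p up to 0.186) and in a fit of these arrays alone.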

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

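The tests of array quality, labels, controls and cell types in this part were chosen after the result was seen, as was the removal of the mean effect below; the other counts over splits of the arrays were fixed before. The effects at 32 h and 8 h differed for 811 genes with hHGF, 272 with NK2 and 600 with mHGF, by a test of the difference itself. The signal of GAPDH control probe sets, which no comparison used, was 0.97 higher at the 3' than at the 5' end for hHGF at 32 h, replicate 3, against -0.02 to 0.12 on the 9 untreated arrays.

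Of 100 splits of the arrays, 2 gave as many genes as the 811 for hHGF, 4 as many as the 600 for mHGF and 5 as many as the 272 for NK2, the real split included. These counts do not decide about chance. Exchanging the labels at 1 of the 2 times turns the difference of the effects into their sum. That split gave the highest counts, 2169, 1885 and 811 for hHGF, mHGF and NK2. With that split and the real split set aside, the highest counts were 647, 926 and 556. For mHGF and NK2 other splits thus also exceeded the real count, which the exchange does not account for. Chance is not argued against for these ligands. With the mean effect of the ligand at both times taken out of the treated arrays, 1 of the 100 splits, the real one, gave as many genes with each ligand, and the highest counts of the others were 174, 66 and 1. The mean effect was estimated with the real labels. Its removal leaves the real count as it is and takes away, by construction, any difference in the split with labels exchanged at 1 time. These counts do not decide about chance either.

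The first pattern is the shared response at 16 h, where 2029 genes were called in the same direction with all 3 ligands. Over these genes the untreated 16 h arrays lay -0.51 ± 0.13 (SD, n = 3 arrays) from the other untreated groups along the direction of the calls, against 0.10 for hHGF, 0.08 for NK2 and 0.13 for mHGF. The genes were chosen for differing from these same arrays, so part of this departure follows from the choice. Without that choice, 4455 genes were called between the untreated 16 h group and the other untreated groups. Most of the shared response may therefore be a property of the untreated 16 h cells or arrays. Degraded RNA in the untreated 16 h arrays is argued against, as 0 of them lay outside the ACTB 3' to 5' range of the ligand-treated 16 h arrays, 2.13 to 2.45. Ligand action stays open: 164 of the 2029 genes (8.08%) were called in that direction against the other untreated groups with all 3 ligands, and time and control cannot be told apart for the rest. No label gives a day or batch for these arrays.

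The second pattern is hHGF at 32 h, replicate 3, with a residual SD of 0.318 against a median of 0.140. Its GAPDH difference of 0.97 is consistent with a 3' bias of degraded RNA, as is its ACTB difference of 3.47. Endothelial cells, fibroblasts and leukocytes are argued against: their markers moved alike by 0.16, 0.20 and 0.18, at median levels of 5.24, 4.39 and 4.17. These lists cannot show cells of another epithelial or tumour line, which were not tested. A wrong label is argued against too, since its mean correlation with its own group, 0.984, exceeded the highest with another group, NK2 at 16 h, by 0.00216. No biological explanation was tested.

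The third pattern is the lower expression of cholesterol synthesis genes with NK2 at 8 h. Untreated 8 h arrays standing apart are argued against, because the list had a median of -1 (quartiles -1.43 and -0.612) against both HGFs at 8 h, with 18 of 18 members below 0. An exchange of the NK2 8 h with the untreated 16 h arrays might give such a pattern; a first test on the NK2 arrays did not decide (differences of -0.000452, 0.00027 and -0.000289 in mean correlation), and a second, added afterwards, found each untreated 16 h array closer to the ligand-treated 16 h arrays than to 8 h arrays, by 0.00371 or more. A wrong label of the NK2 8 h arrays without a partner was not excluded by these values. The mean of this list was 8.948, 9.091 and 9.873 in the NK2 8 h, untreated 16 h and untreated 8 h groups. In that order the means were 7.111, 7.215 and 6.785 for TGF-beta targets and 9.853, 9.964 and 9.484 for mitotic genes. ATF4 targets went otherwise, at 8.855, 9.552 and 8.78, as did G1/S genes, at 9.563, 8.923 and 9.349. What the NK2 8 h and untreated 16 h groups had in common was not tested. It also stays open whether NK2 itself or its higher dose acted, since 1 NK2 dose was given.

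For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. Against untreated cells the real counts and the highest of other splits were 717 and 1, 3890 and 196, and 2559 and 3 for hHGF at 8, 16 and 32 h. They were 1502 and 4, 3075 and 0, and 11 and 0 for NK2, and 695 and 15, 3675 and 0, and 1676 and 0 for mHGF. Between hHGF and NK2 they were 1172 and 0, 263 and 1, and 1974 and 2, and between hHGF and mHGF 351 and 6, 0 and 0, and 2394 and 98. For untreated cells over time they were 2166 and 1. In each of these 1 split, the real one, gave as many genes, except hHGF against mHGF at 16 h, where limma called 0 genes in all 10 splits.

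For the averages over times, 1 of 100 splits, the real one, gave as many genes in each comparison, a share under 0.05. The splits cannot tell a ligand effect from a difference of culture or processing shared by a group. The averages included the 16 h groups, and no splits of the averages were run without them. The real counts and the highest of the other splits were 4072 and 1299 for hHGF, 2148 and 584 for NK2 and 3249 and 1326 for mHGF. They were 1417 and 629 between hHGF and NK2, 2473 and 1334 between hHGF and mHGF and 1509 and 1061 between mHGF and NK2.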

How the results depend on the processing

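The comparisons with another control at 16 h and with 8 h and 32 h only were chosen after seeing the data; the other alternatives were fixed before. Unless a cause is given, the cause was not tested.

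With the replicate number as a block, no count moved by more than 1.5 times. The counts were 720, 3864 and 2570 for hHGF at 8, 16 and 32 h, 1521, 3059 and 12 for NK2, and 678, 3679 and 1662 for mHGF. For 24 of 36 arrays the closest array of another group at the same time had the same number, but the mean correlation of residuals was 0.0247 (-0.194 to 0.211) for the same number and -0.0124 (-0.183 to 0.178) for different numbers. Numbers without meaning would match less often than in 24 of 36 arrays, so a pairing within a time is not ruled out. The block fitted was common to all times and did not test such a pairing. In the main fit the numbers were not used to pair the arrays.

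In a fit of the compared groups alone, which estimates the spread from fewer arrays, the counts against untreated cells were 279 for hHGF at 8 h, 22 for hHGF at 32 h, 0 for NK2 at 32 h and 0 for mHGF at 8 h, each by limma. They were 92 and 1 between hHGF and NK2 at 16 and 32 h, and 0 and 0 between hHGF and mHGF at 8 and 32 h, where the fit of all groups called 351 and 2394. Averaged over times, NK2 gave 3397 and hHGF against mHGF 746. The differences of 32 h and 8 h effects gave 63, 587 and 160 for hHGF, NK2 and mHGF.

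The mean of all probe sets gave 7 genes for NK2 at 32 h. Restricted to genes above the median expression, 433 genes were called between hHGF and NK2 at 16 h, 1248 and 1060 for the 32 h against 8 h effects of hHGF and mHGF, and 1368 for untreated cells over time. Cyclic loess gave 165 between hHGF and mHGF at 8 h. Weighting the arrays, with weights of 0.091 for hHGF 32 h replicate 3 and 0.213 for mHGF 8 h replicate 1, raised most counts. For hHGF they were 1636 and 6333 at 8 and 16 h, for NK2 2635, 5989 and 382 at 8, 16 and 32 h, and for mHGF 429, 6827 and 3652. The averages gave 4631 for NK2 and 4928 for mHGF. Between hHGF and NK2 there were 2490 at 8 h, 1040 at 16 h and 2508 averaged, between hHGF and mHGF 18 at 16 h and 1317 at 32 h, and between mHGF and NK2 3609 averaged. The 32 h against 8 h effects gave 1302, 1054 and 1082, and untreated cells over time 3826.

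Leaving out 1 array left fewer arrays per group. The counts then ranged from 260 to 387 for hHGF, 887 to 1084 for NK2 and 178 to 971 for mHGF at 8 h. They ranged from 2309 to 4016, 1852 to 3151 and 2350 to 3708 at 16 h, and from 1112 to 3875, 0 to 38 and 775 to 1543 at 32 h. Between hHGF and NK2 the ranges were 673 to 825, 78 to 134 and 423 to 3682 at 8, 16 and 32 h, and between hHGF and mHGF 45 to 494 at 8 h and 682 to 3623 at 32 h. For the 32 h against 8 h effects they were 413 to 2141, 161 to 210 and 231 to 974 for hHGF, NK2 and mHGF, and for untreated cells 1135 to 1682. Without hHGF 32 h replicate 3 the counts were 1112 against untreated, 423 against NK2 and 682 against mHGF.

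Against the untreated 8 h and 32 h groups, NK2 at 16 h gave 925 genes, and 23 changes of named genes that were called against at least 1 of the 2 controls turned their sign. With hHGF these were LXN 0.65, DUSP6 0.08, SPRY2 0.06, FOSL1 0.049, PLAU 0.033, PLAUR 0.63, MMP1 0.72, VIM 0.14 and CXCL8 0.97. With NK2 these were LXN 0.29, DUSP6 0.15, PLAUR 0.17, MMP1 0.21, VIM 0.077, CCND1 -0.32, CXCL8 0.93 and MKI67 0.74. With mHGF these were LXN 0.16, IL1B 0.49, SPRY2 0.028, PLAUR 0.37, MMP1 0.38 and CXCL8 0.42. The cholesterol synthesis list turned from higher to lower with all 3 ligands (adjusted p = 0.000609, 6.44e-15 and 7.54e-08). These turns came with the change of control. The other untreated arrays differ in time as well, so time and control cannot be told apart as the cause.

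With 8 h and 32 h only, the averaged counts were 2169, 811 and 1885 for hHGF, NK2 and mHGF. Changes called in at least 1 of the 2 versions that turned their sign were SCNN1G 0.012, MMP1 0.44 and CXCL8 0.54 with NK2, and FOSL1 0.29, PLAUR 0.39, MMP1 0.75 and CXCL8 0.61 with mHGF.

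Of the gene list tests 122 were called, against 44 with an estimated correlation, 125 with the block and 155 with fry. The correlation between responses to hHGF and mHGF at 8 h was 0.671 for genes above the median expression. Among genes called in either contrast, a choice that by construction favours changed genes, it was 0.775 for hHGF and mHGF at 8 h and 0.955 at 16 h. It was 0.890 for hHGF and NK2 and 0.937 for NK2 and mHGF at 16 h, and 0.596 and 0.720 for these pairs at 32 h.

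The results for single named genes kept direction and call in 685 of their tests with cyclic loess, with 10 gained and 9 lost. With the block they did so in 696, with 5 gained and 3 lost, and in the fit of the compared groups alone in 589, with 13 gained and 102 lost. Without single arrays 6464 were the same, 40 were gained and 300 were lost. Calls of signal over background were not used, so genes near the background were not set apart, and the added log2 change of 0.5 was recovered for 34.3% of genes.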

Other observations

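The metallothionein genes, which encode zinc-binding and copper-binding proteins, were chosen after their values were seen. With NK2 at 8 h, 6 of 7 measured genes were called higher, at a median of 0.90, among them MT1F 2.01 ± 0.17 and MT1X 1.14 ± 0.14 (SE, n = 3). At 32 h 5 of 7 were called lower with hHGF at a median of -0.88, among them MT1X -1.12 ± 0.14 and MT2A -0.99 ± 0.14, and 4 of 7 with mHGF at -0.77. Scaled by cyclic loess, the same numbers of genes were called in the same directions, at medians of 0.89, -0.82 and -0.70.

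Between hHGF and NK2, 4 of 7 metallothionein genes were lower with hHGF at 8 h and 5 of 7 at 32 h. Zinc was not measured, and no explanation was tested.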
